A study of Rattus norvegicus with 24 samples.

How the data were processed

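RNA was sequenced from bulk dorsolateral striatum (DLS) and nucleus accumbens (NAc) of male Sprague-Dawley rats sampled on postnatal day 90. Per the labels' protocols, each region was dissected from coronal brain slices, RNA was extracted on RNeasy columns, and poly(A)-selected, strand-specific libraries were made with the NEBNext Ultra Directional kit. The 24 libraries fall into 8 groups of 3, defined by region, by prenatal exposure (lipopolysaccharide, LPS, or saline given to the dam on gestational days 15 and 16) and by peripubertal stress or handling without stress. The labels do not say whether a DLS and an NAc library came from the same rat or which rats shared a litter, so p-values measure the spread between these samples.

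Per the submitters' processing notes, reads were processed with STAR 2.6.25.17 and Cuffdiff 2.2.1. The role of each tool, the annotation and the genome build are not given in the sources used here. Loci are printed as the deposited table lists them, and no reference annotation was used to place exons, introns or untranslated regions.

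The authors deposited 1 table with a column per library, headed as FPKM, but the deposited values are digit strings without a decimal separator and were treated as a score rather than as FPKM. The table holds 415272 values for 17303 genes. Of these values 97026 are listed as 1 and 12, in 4 genes, are blank. Among the values above 1, 89.98% have 6 digits, 9.017% have 5 and 0.8997% have 4, and the largest is 999996. A value is therefore known only up to a power of 10.

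Relative expression was recovered gene by gene. The log10 digits of a gene were placed on a circle on which a full turn is a factor of 10. A gene was used only if its libraries lay within an arc of 0.5 decades, a 3.162-fold range, and its values were then read as log2 differences along that arc. Genes listed as 1 or blank in any library of the fit were left out. This left 9275 genes in DLS (of 12091 above 1 in all its libraries), 10616 in NAc (of 12496) and 7667 over both regions (of 12001). The share of genes with random digits that would fall within the arc is 0.00586 in a region, or 16.6 genes in DLS and 11.1 in NAc if all excluded genes were random. Absolute levels and sequencing depth are unknown, and no interval that needs counts was computed. A gene whose libraries span more than 3.162-fold is left out, and a larger difference between groups can appear with the opposite sign.

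Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without a trend), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each region was fitted alone, with a mean for each of its 4 groups and 8 residual degrees of freedom. The contrasts were the main effects of LPS and of stress, their interaction, and each of the 3 exposed groups against saline unstressed controls. A fit over all 24 libraries with 8 group means gave the region comparison and the differences between regions. The comparisons against one control group share its libraries. Gene lists, 42 in number, covered transmitter systems, cell types, immune and stress pathways and housekeeping complexes. Those with at least 5 tested members (34 in DLS, 39 in NAc, 26 over both regions) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List indices are means of the members' relative log2 values per library.

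The groups, contrasts, gene lists and named-gene rule were fixed before the data were examined. So were rescaling, array weights, estimated correlation, fry, the library number as a block, the fit of all 24 libraries and leaving out each library. The rule named up to 10 higher and 10 lower genes with the largest differences among those past the threshold, or, where fewer than 10 passed, the genes with the smallest p up to 10. It added the 4 list members with the smallest p and a fixed set of striatal, stress and glial genes. Genes without a symbol were counted, and named only where fewer than 10 genes passed. That plan assumed usable FPKM values. The recovery on the circle and its arc of 0.5 decades were chosen after the values had been seen. A pseudocount, a filter on mean FPKM and a variance trend on expression cannot be applied to digits without a decimal point, so the fits use none of them. Other arcs (0.3 and 0.7), robust empirical Bayes, covariates for the ribosomal index or a principal component, and leaving out 2 NAc libraries together were added later.

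The procedure was tested on simulated digits, with 50 genes changed at each fold. For the stress main effect, 50% of 1.5-fold and 56% of 2-fold changes were recovered in DLS, and 66% and 62% in NAc. For LPS alone against control the shares were 12% and 52% in DLS, and 18% and 54% in NAc. Changes of 3-fold were recovered in 0% in DLS for both contrasts, and in NAc in 2% for the stress main effect and 0% for LPS alone. Of 8-fold changes in the stress main effect, 7 in DLS and 12 in NAc were called in the wrong direction. No pair of replicates was a duplicate, since the smallest standard deviation of the difference between libraries of a group was 0.23 log2 in DLS and 0.22 in NAc.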

Results

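The series asks how immune activation during pregnancy and stress around puberty act, alone and together, on gene expression in the striatum of adult male rats. LPS is a component of the outer membrane of Gram-negative bacteria that triggers innate immunity, and it was given to the dam. The dorsolateral striatum (DLS) serves habitual action and the nucleus accumbens (NAc) serves motivation and reward. Each of the 8 groups held 3 libraries, and saline unstressed offspring were the controls. Values are relative log2 expression, with a standard deviation (SD) over 3 libraries or a standard error (SE) from limma. Gene lists are described where they passed camera at its preset correlation. Some lists share genes, such as C1qb (complement and microglia) and Gpr6 (dopamine signalling and indirect-pathway), so calls of such lists are not separate evidence. Their medians without 1 library are given mainly where they shrank or turned, and in many lists the median also grew by over 1.5 times without another library. The difference in a comparison with controls uses only the libraries of the exposed group and of the controls. Its error, and the genes tested, draw on all 4 groups of the region. Fits that left out a library of another group kept both of these means. Passing there says little about the stability of the difference, although counts of genes and lists could still move. The depth of the libraries is unknown, and the number of genes listed as 1 ran from 3838 to 4463 per library. The median 95% interval of a difference from control reached 0.418 log2 to either side in DLS and 0.360 in NAc. When 3 libraries are set against 3, an unchanged gene has all its treated libraries on 1 side of all controls with a chance of 10%. This chance holds for a gene chosen without regard to its values, such as those fixed in advance. Most genes described below as above or below every control were instead named for their small p, among all genes tested or within a list. Their separation from the controls follows largely from that choice and is not separate evidence of a difference. Differences above about 3.162-fold lie outside what these values can show, and simulated 3-fold changes were nearly all left out as well. Of simulated 2-fold changes 52% to 62% were recovered, so a count of 0 speaks only in part, and only for changes up to about that size. Of 1.5-fold changes with LPS alone 12% and 18% were recovered. The simulation covered only the stress main effect and LPS alone, with noise independent between genes. It took its spread from the genes within the arc, so its shares do not cover the genes that the arc left out. Interactions had a larger median SE (0.271 in DLS, against 0.136 for a DLS main effect), as did differences between regions, so their counts of 0 speak less. The deposited loci of Anks4b, Cacna1h, Cacng8, Capn12, Clu, Dcp2, Fhl4, Igf2, Mog, Rhbdl3, RT1-CE5, Slc7a10 and Tnfaip8l2 hold more than 1 gene, so the values of these genes are uncertain.

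In DLS, no single gene passed the adjusted threshold between stressed saline offspring and controls. Ribosomal, complement, mitochondrial and glial gene groups stood higher in them, but only as long as members of a group were taken as nearly independent. Aif1, which encodes the microglial protein Iba1, was 1.02 ± 0.38 (SD, n = 3) above the control mean and lay above all controls in 3 of 3 libraries. Within groups Aif1 also ran with the ribosomal index, at 1.28 and 0.08 in LPS stressed replicates 1 and 3, whose index was 0.49 and -0.47. At near-equal indices of 0.00, 0.01 and 0.04, Aif1 stood at 1.02 and 0.65 in stressed saline replicates 2 and 3 and at 0.30 in control replicate 2. With the ribosomal index as covariate Aif1 did not pass. It did not pass without the covariate either, so this fit cannot decide whether the axis accounts for its difference. The complement gene C1qa was at 0.92 ± 0.36, the lysosomal protease gene Ctss at 0.78 ± 0.41 and the astrocyte gene S100b at 0.71 ± 0.34, each above all controls in 3 of 3 libraries. Below all controls in 3 of 3 were Epb4.1l5, a cytoskeletal adaptor (-0.92 ± 0.22; chromosome 13, 40736725 to 40787937), and Unc79, a subunit of the sodium leak channel complex (-1.17 ± 0.34; chromosome 6, 136068612 to 136268418). Ldb2, a LIM-domain binding factor, stood at -1.05 ± 0.40 and the kinase gene Rps6ka6 at -1.03 ± 0.24.

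By list, 11 of 12 complement and antigen presentation genes were higher in stressed saline offspring (median 0.51, camera adjusted p = 0.000206), as were 18 of 23 astrocyte markers (median 0.36) and 14 of 18 microglia markers (median 0.30). None of these 3 calls held with an estimated correlation (adjusted p = 0.664 with an estimated correlation for each). Over all genes 0 members of the 3 lists passed, and adjusted over the list alone 5, 4 and 4 did. Apoe (0.70), Clu (0.59) and Aldh1l1 (0.58) were the leading astrocyte members after S100b, and C1qb (0.69), RT1-A2 (0.57) and Psmb8 (0.89) led the complement list. RT1 genes belong to a multigene family whose reads can be shared, so their values are uncertain. Cytosolic ribosomal protein genes (54 of 56, median 0.55) and nuclear oxidative phosphorylation genes (57 of 59, median 0.49) were also higher. In the other direction lay 16 of 19 presynaptic release genes (median -0.22; Unc13a -0.66) and 14 of 20 voltage-gated channel genes (median -0.19). The calcium channel genes Cacna1d and Cacna1h were both at -0.66. These 4 lists had an adjusted p = 0.664 with an estimated correlation too, and adjusted over the list alone 0, 0, 0 and 2 of their members passed. The ribosomal index itself was uneven among the controls, at -0.50, 0.04 and -0.50 in replicates 1, 2 and 3. The complement, ribosomal and oxidative phosphorylation lists passed in all 12 fits with 1 library left out, and astrocyte and microglia markers in 11 and 10. Relative to their size, microglia, astrocyte, oxidative phosphorylation and channel medians shrank most. They fell to 0.19 without stressed replicate 2, to 0.24 and 0.31 without stressed replicate 1 and to -0.11 without control replicate 1. The ribosomal and complement medians grew to 0.73 and 0.65 without control replicates 2 and 3, and the astrocyte one to 0.49 without stressed replicate 3.

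The remaining genes with the smallest p were Zcchc11, a terminal uridylyltransferase (-0.66), Dffb, the caspase-activated DNase (-0.67), Slc25a27, a mitochondrial carrier (-0.72), Prrt4 (-0.81), Snx20 (0.81) and Mrgprx3 (1.09), a member of a receptor family with close relatives whose value is uncertain. At the level of single genes 0 of 9275 passed with limma, with an adjusted p = 0.294 for each of the 10 named by smallest p. At an unadjusted p under 0.05 there were 1358 genes (770 higher, 588 lower), where 463.8 are expected by chance. The count was 491 without stressed saline replicate 1, 684 without control replicate 3 and 752 without control replicate 1, and it reached 1847 without LPS stressed replicate 3. With array weights 1186 genes passed, against up to 4469 in regrouped libraries. With the first component of the residuals as covariate 1581 passed, against up to 707 in regrouped libraries, whose 10 splits are too few to exclude chance. Elsewhere in DLS only the stress main effect (676) and the interaction (481) exceeded the 463.8 genes expected at an unadjusted p under 0.05. The LPS main effect (149), LPS alone (301) and both exposures (303) fell below it. In NAc 530.8 are expected, and every comparison fell below that, at 95 to 377.

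Averaged over both prenatal exposures, stressed DLS libraries had higher values of N5 (0.62 ± 0.11 SE; 3 of 3 above controls in both stressed groups), Islr, a gene of fibroblast-like cells (0.67 ± 0.13), and Fcgr3a, an immunoglobulin receptor of microglia (0.48 ± 0.11). Lower were Rps6ka6 (-0.65 ± 0.14) and Ldb2 (-0.62 ± 0.14). The N5 locus in the deposited table (chromosome 4, 57272128 to 57387292) holds 2 genes, whose values are uncertain. Gprc5c (0.64), Rad9b (0.75), Anks4b (0.61) and Galnt3 (0.67) were also among the 10 genes with the smallest p. All 12 complement and antigen presentation genes (median 0.35; Psmb8 0.64, RT1-A1 0.48) and 10 of 11 leptomeningeal and fibroblast markers (median 0.32; Lum 0.40, Igfbp2 0.53) were higher. The respective values were adjusted p = 0.594 and adjusted p = 0.298 with an estimated correlation. Astrocyte markers (17 of 23, median 0.21), microglia markers (14 of 18, median 0.17), immediate early genes (14 of 19, median 0.11; Nr4a1 0.55, Egr2 0.59, Junb 0.36), interferon response genes (12 of 14, median 0.21), ribosomal protein genes (55 of 56, median 0.31) and oxidative phosphorylation genes (55 of 59, median 0.20) were higher too. Presynaptic release genes (16 of 19, median -0.22), GABA receptor and synthesis genes (8 of 10, median -0.21; Gad2 -0.63, Gabra2 -0.50) and voltage-gated channel genes (16 of 20, median -0.13) were lower. In the order given, adjusted p = 0.695, 0.695, 0.594, 0.708, 0.708, 0.749, 0.695, 0.594 and 0.708 with an estimated correlation. Adjusted over the list alone only Islr passed among the 11 lists. Complement and ribosomal genes passed in all 12 fits with 1 library left out, interferon response genes in 5, and GABA genes and immediate early genes in 6. The interferon, presynaptic, channel and GABA medians shrank to 0.08, -0.11, -0.05 and -0.13 without LPS stressed replicate 1, the ribosomal and oxidative phosphorylation medians to 0.18 and 0.06 without LPS unstressed replicate 3, and the leptomeningeal and astrocyte medians to 0.16 and 0.13 without control replicates 1 and 2. The immediate early gene median was 0.06 without saline stressed replicate 2 and 0.17 without LPS unstressed replicate 2. No single gene stood out by limma, where 0 of 9275 passed (smallest adjusted p = 0.637), and 676 had an unadjusted p under 0.05 (353 without stressed saline replicate 1, 2162 without LPS stressed replicate 3). Array weights gave 217 genes and the residual component 579.

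Prenatal LPS without later stress was accompanied in DLS by lower Gli2, a hedgehog pathway transcription factor (-1.11 ± 0.35 SD, n = 3), Magix (-1.09 ± 0.31), Prrt4 (-0.74 ± 0.12) and Celsr3, an adhesion receptor of axon guidance (-0.62 ± 0.10). All 4 lay below every control in 3 of 3 libraries. Capn12, a calpain protease gene, was higher (0.66 ± 0.14, 3 of 3 above controls), and Dcp2, an mRNA decapping enzyme, was at 0.76 ± 0.21 SE. Tnfaip8l2 (0.73), Nudt22 (0.65), Dnajc25 (0.53) and Rhbdl3 (-0.49) followed. Complement and antigen presentation genes (9 of 12, median 0.34; C1qa 0.70), microglia markers (13 of 18, median 0.26; Ctss 0.61, Trem2 0.65), myelin genes (27 of 30, median 0.17; Pllp 0.35), ribosomal protein genes (56 of 56, median 0.35) and oxidative phosphorylation genes (58 of 59, median 0.38) were higher. These 5 lists had an adjusted p = 0.877 with an estimated correlation. In the ribosomal index LPS replicate 3 stood at -0.52, below every control, and replicates 1 and 2 at 0.20 and 0.41. Without replicate 3 the ribosomal and oxidative phosphorylation medians were 0.63 and 0.61, and without replicate 2 they were 0.17 and 0.21. Without replicate 2 the complement and microglia medians also fell to 0.17 and 0.15, and they passed in 10 and 9 of the 12 fits with 1 library left out, while the leptomeningeal median was -0.41. The endothelial median was 0.02 without control replicate 3. Endothelial and pericyte markers (17 of 20 lower, median -0.17; Tagln -0.89) and leptomeningeal markers (9 of 11 lower, median -0.19; Col3a1 -0.49) went the other way, with adjusted p = 0.879 and adjusted p = 0.607 with an estimated correlation. Adjusted over the list alone 0 members passed in any of the 7 lists, and likewise over all genes. With limma 0 of 9275 genes passed (smallest adjusted p = 0.967), and 301 had an unadjusted p under 0.05. Array weights gave 2469 genes, against up to 3497 in regrouped libraries.

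Averaged over stress, LPS offspring had higher DLS values of Pemt, the phosphatidylethanolamine methyltransferase (0.63 ± 0.13 SE), Dnajb14 (0.55), Capn12 (0.49), Ctsk, a cathepsin (0.56), and Ube3d (0.55). Their values of Plk5 (-0.67 ± 0.14), F3, which encodes tissue factor (-0.57 ± 0.13), Gli2 (-0.77), Lyve1, a marker of perivascular macrophages and lymphatic endothelium (-0.73), and Fgfrl1 (-0.35) were lower. Relative to controls, Pemt was at 0.30 ± 0.11 (SD, n = 3) with LPS alone and at 0.33 ± 0.17 with both exposures, and at -0.64 ± 0.41 with stress alone. All 9 indirect-pathway projection neuron markers (median -0.16; Adora2a -0.21, Drd2 -0.25), 13 of 15 dopamine signalling genes (median -0.11; Ppp1r1b -0.24), 16 of 20 endothelial and pericyte markers (median -0.07; Pdgfrb -0.27) and 17 of 23 astrocyte markers (median -0.07) were lower, each with an adjusted p = 0.813 with an estimated correlation. Leptomeningeal markers were lower in 9 of 11 (median -0.17; adjusted p = 0.470 with an estimated correlation). Ribosomal protein genes (54 of 56, median 0.13), oxidative phosphorylation genes (54 of 59, median 0.10), complement genes (10 of 12, median 0.10), presynaptic genes (16 of 19, median 0.09) and glucocorticoid-responsive genes (12 of 15, median 0.04; Sgk1 0.38) were higher, again with an adjusted p = 0.813 with an estimated correlation. Adjusted over the list alone only F3 passed. None of the 10 lists passed in all 12 fits with 1 library left out, and the ribosomal list came closest with 10. The presynaptic median turned to -0.03 without LPS stressed replicate 3 and the endothelial one to 0.01 without control replicate 3. Complement and oxidative phosphorylation medians shrank to 0.02 each without LPS unstressed replicate 2, ribosomal and indirect-pathway ones to 0.04 and -0.09 without LPS stressed replicate 1, dopamine and leptomeningeal ones to -0.05 and -0.07 without LPS unstressed replicate 1, and the astrocyte one to -0.03 without saline stressed replicate 1. At the level of single genes 0 of 9275 passed with limma (smallest adjusted p = 1.00), and 149 had an unadjusted p under 0.05. At an arc of 0.3 decades 0 lists passed in place of 10.

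The interaction, the question named in the title, asks whether stress moved a gene differently in LPS than in saline offspring. In DLS the largest estimates among the genes with the smallest p were Tagln, a smooth muscle cytoskeletal gene (1.37 ± 0.36 SE), Magix (1.31 ± 0.32), Pnlip, pancreatic lipase (-1.23 ± 0.29), and Zbtb25 (1.17 ± 0.30). Pnlip stood above controls at 0.66 ± 0.35 (SD, n = 3) with stress alone and at 0.59 ± 0.23 with LPS alone, and at 0.01 ± 0.32 with both. Nfkbib, an inhibitor of NF-kB, and Cope, a coatomer subunit, had negative terms (-0.74 and -0.86). Slc38a6 (1.05), Prrt4 (0.98), Epb4.1l5 (0.98) and Celsr3 (0.96) had positive ones. Oxidative phosphorylation genes (58 of 59, median -0.55; Uqcr10 -1.25, Atp5b -0.49), ribosomal protein genes (51 of 56, median -0.51; Rplp0 -0.55), myelin genes (26 of 30, median -0.31; Pllp -0.64, Gal3st1 -0.69) and astrocyte markers (17 of 23, median -0.25; Aldh1l1 -0.64, Apoe -0.73) had negative terms. The ribosomal list no longer passed without LPS stressed replicate 3 (median -0.17, adjusted p = 0.195) or LPS unstressed replicate 2 (median -0.30, adjusted p = 0.0658), while oxidative phosphorylation genes passed in all 12 fits with 1 library left out, with a median of -0.31 without LPS stressed replicate 3. Astrocyte and myelin medians shrank to -0.12 and -0.21 without LPS stressed replicate 1. Each list had an adjusted p = 0.770 with an estimated correlation, and 0 of their members passed over all genes or adjusted over the list alone. No single gene stood out by limma, where 0 of 9275 passed (smallest adjusted p = 0.829), and 481 had an unadjusted p under 0.05. The median 95% interval of an interaction term reached 0.590 to either side, wider than that of a single comparison.

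LPS offspring that were also stressed had DLS values of Ctss at 0.84 ± 0.26 (SD, n = 3), Fcgr3a at 0.64 ± 0.03, N5 at 0.70 ± 0.23 and Capn12 at 0.67 ± 0.08, all above every control in 3 of 3 libraries. Dffb (-0.58 ± 0.15) lay below every control in 3 of 3. Prss36 (0.94 ± 0.24 SE), Galnt3 (0.84), Psme4, a proteasome activator (-0.68), and Gtpbp4, a ribosome assembly GTPase (-0.63), were also among the 10 genes with the smallest p. All 12 complement and antigen presentation genes were higher (median 0.43; RT1-A1 0.80, B2m 0.53, Psmb8 0.80), as were 14 of 18 microglia markers (median 0.29), though the homeostatic microglial receptor gene P2ry12 stood at -0.65. Ribosomal protein genes (55 of 56, median 0.44), oxidative phosphorylation genes (56 of 59, median 0.31) and interferon response genes (12 of 14, median 0.18; Ifi44 0.63) were higher, and GABA receptor and synthesis genes lower (8 of 10, median -0.24). Without LPS stressed replicate 1 the interferon median was 0.01, the GABA one -0.11 and the ribosomal one 0.24, and these lists passed in 7, 8 and 12 of 12 fits with 1 library left out. Without LPS stressed replicate 3 the ribosomal, oxidative phosphorylation and microglia medians were 0.74, 0.57 and 0.17, and without replicate 2 the oxidative phosphorylation one was 0.16. All 6 lists had an adjusted p = 0.682 with an estimated correlation, and adjusted over the list alone only Ctss passed, in the microglia list. With limma 0 of 9275 genes passed (smallest adjusted p = 0.908), and 303 had an unadjusted p under 0.05. Array weights gave 2507 genes, and up to 5478 in regrouped libraries.

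**Figure D1:**
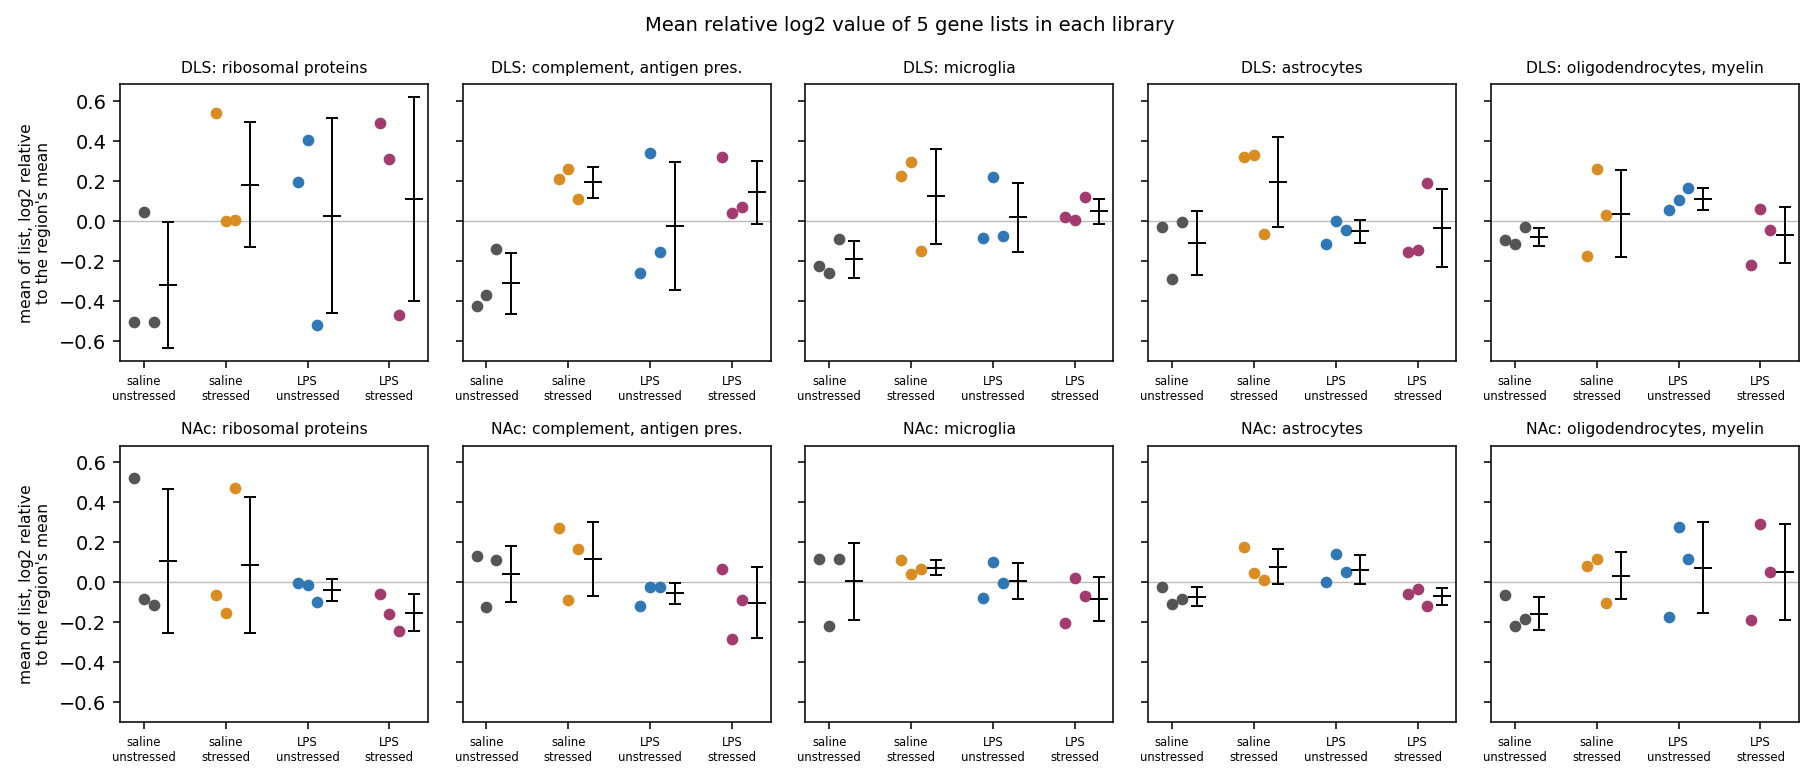
Mean relative log2 value of 5 gene lists (vertical axis, relative to the region's mean) in each of the 24 libraries by group, with DLS above and NAc below; points are libraries, and the bar shows the mean and SD of 3. The DLS complement index lies at -0.31 ± 0.15 in controls and 0.19 ± 0.08 in stressed saline offspring, and ribosomal indices spread widely within groups.

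Among the genes fixed in advance for DLS, the dopamine receptor genes Drd1 and Drd2 and the glucocorticoid-related genes Fkbp5 and Nr3c1 did not pass in any exposed group. For stress alone the values were -0.16 ± 0.23 (SE) for Drd1, 0.06 ± 0.30 for Drd2, 0.11 ± 0.18 for Fkbp5 and -0.08 ± 0.19 for Nr3c1. The opioid precursor gene Penk was at 0.63 ± 0.31, the astrocyte gene Gfap at 0.56 ± 0.26 and the immediate early gene Fos at 0.53 ± 0.26, with adjusted p = 0.366, 0.341 and 0.362 by limma. Pdyn (-0.15), Tac1 (0.40), Mbp (0.25) and Tlr4, the LPS receptor gene (0.01), did not pass either. Bdnf, Crh, Il1b and Ttr were not testable in either region, and Fos was not testable in NAc.

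**Figure D2:**
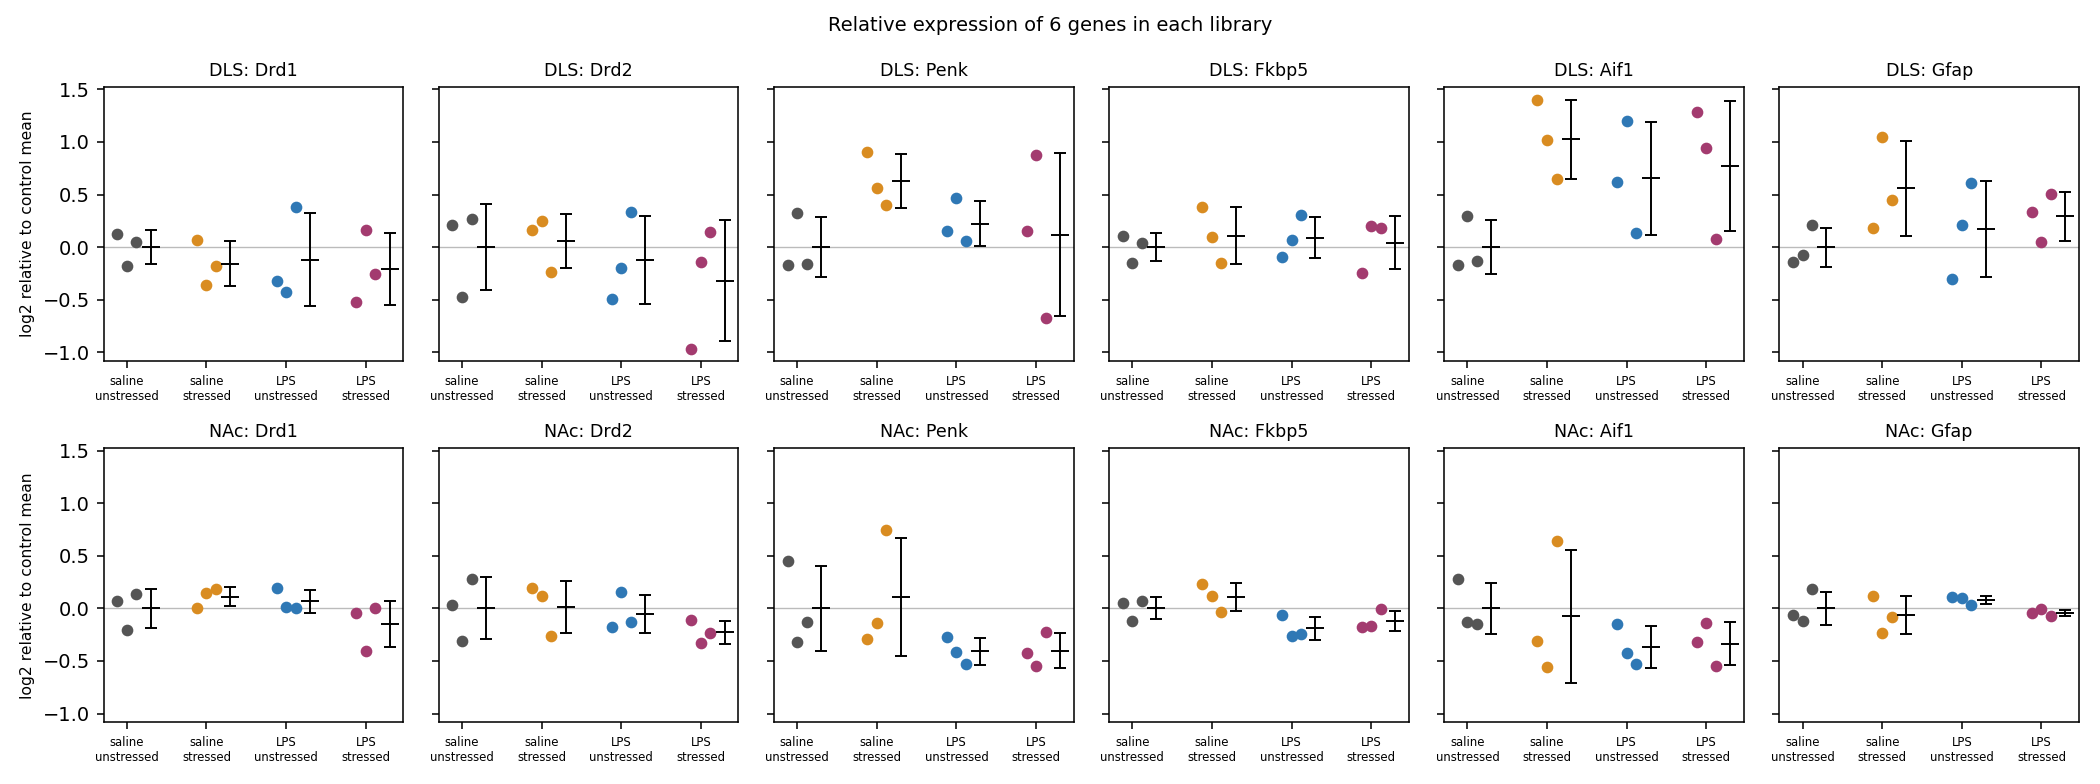
Relative log2 expression of Drd1, Drd2, Penk, Fkbp5, Aif1 and Gfap (vertical axis, relative to the control mean of the region) in each library by group, with DLS above and NAc below; points are libraries, and the bar shows the mean and SD of 3. Aif1 in DLS lies at 1.02 ± 0.38 in stressed saline offspring, above all 3 controls. Penk in NAc lies at -0.41 ± 0.13 with LPS alone, where control replicates 1, 2 and 3 lie at 0.45, -0.32 and -0.13.

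In NAc, offspring of LPS-treated dams had lower Hpd, an enzyme of tyrosine breakdown (-0.89 ± 0.14 SE; chromosome 12, 40729052 to 40740668), and higher Clca1 (0.60 ± 0.10) and Grid2ip, a scaffold of the delta glutamate receptor (0.69 ± 0.12). Hpd lay below every control in 3 of 3 libraries with LPS alone (-0.92 ± 0.32 SD, n = 3) and in 3 of 3 with both exposures (-0.58 ± 0.38), and above every control with stress alone (0.29 ± 0.07). Map7, a microtubule-associated protein gene (0.31), Nqo2, a quinone reductase gene (0.55), Exoc3l4 (0.71) and Dennd1c (0.52) were higher, and Fam227a (-0.54), Stac3 (-0.80) and Dpysl4 (-0.31) lower. Fkbp5 was at -0.21 ± 0.08 and Penk at -0.46 ± 0.19, with an adjusted p = 0.823 for both. Relative to the control mean, Penk stood at 0.45 in control replicate 1 and at 0.75 in stressed saline replicate 3. In the other 4 saline libraries it lay between -0.32 and -0.13, and in the LPS libraries between -0.55 and -0.23, so its difference rests largely on these 2 saline libraries. Ribosomal protein genes (67 of 68, median -0.20), oxidative phosphorylation genes (66 of 67, median -0.15), complement genes (13 of 16, median -0.15; C1s -0.45), dopamine signalling genes (15 of 16, median -0.14; Ppp1r1b -0.28, Arpp19 -0.32) and indirect-pathway markers (7 of 9, median -0.14; Adora2a -0.22) were lower. Myelin genes (27 of 31, median 0.13; Olig2 0.27), GABA genes (14 of 17, median 0.16), glutamate receptor genes (17 of 21, median 0.10; Grik1 0.48), presynaptic genes (19 of 22, median 0.11) and voltage-gated channel genes (17 of 24, median 0.22) were higher. All 10 lists had an adjusted p = 0.621 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The ribosomal index stood at 0.52 in control replicate 1 and at 0.47 in stressed saline replicate 3, while the other 4 saline libraries lay between -0.16 and -0.06, and the LPS groups averaged -0.04 ± 0.05 (SD, n = 3) and -0.15 ± 0.09. Without these 2 libraries the ribosomal median was 0.01 (adjusted p = 0.442) and the oxidative phosphorylation genes turned higher (0.06, adjusted p = 0.000206), and complement, GABA, glutamate receptor, presynaptic and channel genes no longer passed (medians -0.07, -0.05, -0.04, -0.00 and -0.04). Dopamine signalling (-0.16), indirect-pathway (-0.15) and myelin genes (0.12) still did, though their medians shrank to -0.07 (dopamine) without control replicate 3 and to 0.06 (myelin) without LPS stressed replicate 2. At the level of single genes 0 of 10616 passed with limma (smallest adjusted p = 0.492), and 377 had an unadjusted p under 0.05. The residual component as covariate gave 722 genes, against up to 2579 in regrouped libraries.

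LPS alone in NAc was marked by lower Slc39a11, a zinc transporter gene (-0.52 ± 0.08 SD, n = 3; chromosome 10, 101430090 to 101762931), Tinagl1 (-0.90 ± 0.30) and Clic3 (-0.91 ± 0.22 SE). Grid2ip (0.90 ± 0.15 SD), Exoc3l4 (1.03 ± 0.07), Nqo2 (0.84 ± 0.28), Col15a1, a basement membrane collagen gene (0.64 ± 0.20), Gpr83 (0.50 ± 0.08) and Map7 (0.38 ± 0.03) lay above every control in 3 of 3 libraries. All 31 tested myelin genes (median 0.21; Olig2 0.44, Ugt8 0.41), 16 of 20 astrocyte markers (median 0.13; Glul 0.34), 12 of 14 leptomeningeal markers (median 0.20; Slc6a13 0.73) and 15 of 17 GABA genes (median 0.24) were higher. Ribosomal protein genes (58 of 68, median -0.16), oxidative phosphorylation genes (65 of 67, median -0.18) and endothelial markers (22 of 27, median -0.10; Tie1 -0.42) were lower. All 7 lists had an adjusted p = 0.821 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The lower ribosomal and oxidative phosphorylation genes rest on control replicate 1, whose ribosomal index was 0.52 against -0.09 and -0.11 in the other controls. Without it their medians were 0.04 (adjusted p = 0.0252, now higher) and -0.03 (adjusted p = 0.739), and the endothelial median was 0.11 without LPS replicate 1, while myelin genes passed whichever library was left out (median 0.12 without LPS replicate 2). GABA genes passed in 6 of 12 fits (median 0.07 without control replicate 1), and the leptomeningeal median was 0.09 without LPS replicate 2. No single gene stood out by limma, where 0 of 10616 passed (smallest adjusted p = 0.935), and 325 had an unadjusted p under 0.05. Array weights gave 634 genes and the residual component 19, and regrouped libraries gave up to 629 and 1888.

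Stress alone in NAc was accompanied by lower Slc39a11 (-0.54 ± 0.08 SD, n = 3), Prkcd, a protein kinase C gene (-0.70 ± 0.12), and Tubb6 (-0.64 ± 0.17 SE), and by higher Ccdc68 (0.97 ± 0.07 SD), Col15a1 (0.60 ± 0.20) and Uvssa, a factor of transcription-coupled repair (0.49 ± 0.14). Asgr2 (0.82), Nt5c1a (0.92) and Rbpms2 (0.53) were also among the 10. The circadian activator gene Clock stood at 1.04 ± 0.12 above a control mean whose own SD was 0.73, and Ciart, a repressor of the clock, at -0.96 ± 0.08. These were the 2 of 14 clock genes that passed when adjusted over the list alone, in a list lower in 10 of 14 members (median -0.17, adjusted p = 0.771 with an estimated correlation) and at 0.02 without stressed replicate 3. Myelin genes (30 of 31, median 0.20; Olig1 0.38) were higher (adjusted p = 0.771 with an estimated correlation), as were leptomeningeal markers (13 of 14, median 0.28; Aldh1a2 0.72) and astrocyte markers (17 of 20, median 0.11; Gjb6 0.46), with an adjusted p = 0.193 with an estimated correlation for both. Myelin genes and astrocyte markers passed in all 12 fits with 1 library left out, the latter with medians of 0.06 without control replicate 2 and 0.23 without stressed replicate 3. Ependymal and cilia genes were lower in 5 of 6 (median -0.20; Foxj1 -0.47; adjusted p = 0.771 with an estimated correlation), a call that ended when the libraries were rescaled (adjusted p = 0.0527) although the median was then -0.22, and the median was -0.45 without control replicate 2. With limma 0 of 10616 genes passed (smallest adjusted p = 1), and 137 had an unadjusted p under 0.05. Without control replicate 3, Clock passed at 1.45 (adjusted p = 0.0183).

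Averaged over prenatal exposure, stress in NAc went with lower Spata22 (-0.53 ± 0.12 SE), Cldn19 (-0.66 ± 0.16) and the mitotic kinase gene Ttk (-0.50 ± 0.13), and higher Uvssa (0.41 ± 0.09), Hpdl (0.47), Asgr2 (0.57), Ccdc68 (0.48), Nfe2l3 (0.56), Abhd14a (0.44) and Cdh3, P-cadherin (0.32). All 8 cholinergic interneuron markers (median -0.19; Slc17a8 -0.27, Slc5a7 -0.27), 63 of 68 ribosomal protein genes (median -0.06) and 5 of 6 ependymal genes (median -0.12) were lower. Myelin genes (29 of 31, median 0.07), endothelial markers (22 of 27, median 0.05) and leptomeningeal markers (13 of 14, median 0.14; Igf2 0.25) were higher. None of the 6 lists passed in all 12 fits with 1 library left out, and the ribosomal median was 0.04 without control replicate 1. Without LPS stressed replicate 2 the cholinergic, ependymal and myelin medians were -0.05, -0.03 and 0.02, and the endothelial one turned to -0.03 without LPS unstressed replicate 1. Leptomeningeal markers had an adjusted p = 0.986 and the other lists an adjusted p = 0.993 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. At the level of single genes 0 of 10616 passed with limma (smallest adjusted p = 1), and 95 had an unadjusted p under 0.05.

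For the interaction in NAc, all 20 astrocyte markers had negative terms (median -0.26; Gjb6 -0.68 ± 0.25 SE, Glul -0.45 ± 0.18, Aldh1l1 -0.38 ± 0.14, Slc7a10 -0.33 ± 0.15). Relative to controls Aldh1l1 stood at 0.26 ± 0.03 (SD, n = 3) with stress alone, 0.27 ± 0.14 with LPS alone and 0.16 ± 0.07 with both. This list had the smallest value of the treatment comparisons, adjusted p = 0.0812 with an estimated correlation. The zinc transporter gene Slc39a11 had a positive term (0.77 ± 0.13 SE), since it lay below controls in each exposed group but least with both exposures (-0.29 ± 0.08 SD). Tinagl1 (1.09), Ankrd39 (1.00) and LOC100158225 (0.90) had positive terms, and the protocadherin gene Pcdha11 (-1.21), whose exons can be shared with its neighbours, Ccdc68 (-0.98), Dctd (-0.95), Emx2 (-0.66), Prodh (-0.64) and Gpr83 (-0.63) negative ones. Direct-pathway markers (7 of 8, median -0.24; Drd1 -0.33), dopamine signalling genes (15 of 16, median -0.19), heat shock genes (23 of 26, median -0.15; Hsph1 -0.36), leptomeningeal markers (12 of 14, median -0.23; Aldh1a2 -0.98), microglia markers (16 of 20, median -0.18; C1qc -0.52) and myelin genes (29 of 31, median -0.18) had negative terms, and presynaptic genes positive ones (18 of 22, median 0.13). These 7 lists had an adjusted p = 0.838 with an estimated correlation, and endothelial markers (19 of 27 positive, median 0.17) an adjusted p = 0.851 with an estimated correlation. Of the 9 lists only astrocyte markers passed in all 12 fits with 1 library left out. The endothelial median turned to -0.03 without LPS unstressed replicate 1 and the presynaptic one to -0.03 without saline stressed replicate 3. Medians shrank to -0.04 for dopamine genes without control replicate 2, -0.04 for heat shock genes without control replicate 3, -0.11 for direct-pathway markers without LPS stressed replicate 2, -0.09 for microglia markers without LPS unstressed replicate 2, and -0.09 and -0.13 for myelin and leptomeningeal genes without LPS stressed replicates 1 and 3. Adjusted over the list alone 0 members passed in the 9 lists, as over all genes. No single gene stood out by limma, where 0 of 10616 passed (smallest adjusted p = 1.00), and 189 had an unadjusted p under 0.05.

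With both exposures, NAc values of Col15a1 (0.72 ± 0.10 SD, n = 3), Nqo2 (0.75 ± 0.15), Uvssa (0.60 ± 0.18), Cdh3 (0.56 ± 0.07), Grid2ip (0.71 ± 0.37) and Map7 (0.33 ± 0.05) lay above every control in 3 of 3 libraries. Those of Ttk (-0.73 ± 0.24) and Rpl17 (-1.07 ± 0.08) lay below. Rpl17 has processed pseudogenes that can share its reads, so its value is uncertain. Fam227a was at -0.58 ± 0.15 SE. All 68 ribosomal protein genes (median -0.25), all 67 oxidative phosphorylation genes (median -0.17), 15 of 16 dopamine signalling genes (median -0.17), 8 of 9 indirect-pathway markers (median -0.23; Gpr6 -0.31), 13 of 16 complement genes (median -0.19; Psmb9 -0.45) and all 6 ependymal genes (median -0.30; Drc1 -0.54) were lower. All 14 leptomeningeal markers (median 0.24; Bgn 0.53), 30 of 31 myelin genes (median 0.18), all 8 oligodendrocyte precursor markers (median 0.15), 18 of 21 glutamate receptor genes (median 0.17; Grik1 0.54), 20 of 22 presynaptic genes (median 0.16) and 20 of 24 voltage-gated channel genes (median 0.27; Kcnd3 0.48) were higher. All 12 lists had an adjusted p = 0.638 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Drd1 (-0.15), Drd2 (-0.23), Fkbp5 (-0.12), Nr3c1 (0.08), Aif1 (-0.33), Gfap (-0.04), Mbp (0.15), Pdyn (-0.10), Penk (-0.40), Tac1 (-0.20) and Tlr4 (0.41) did not pass. With limma 0 of 10616 genes passed (smallest adjusted p = 0.962), and 221 had an unadjusted p under 0.05. Without control replicate 1 the ribosomal and oxidative phosphorylation medians were -0.04 (adjusted p = 0.155) and -0.02 (adjusted p = 0.772) in place of those above, and the presynaptic and channel ones 0.08 and 0.10. The leptomeningeal median was 0.06 without LPS stressed replicate 1, myelin and precursor medians 0.08 and 0.06 without LPS stressed replicate 2, the dopamine one -0.08 without control replicate 3 and the glutamate receptor one 0.09 without control replicate 2, where the ependymal and indirect-pathway ones were -0.59 and -0.38.

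Far more genes passed between the regions, with 12 libraries in each, than in any treatment comparison. The largest region difference was 1.15, against 1.37 for the DLS interaction, and the arc limits both. A further 4334 genes lay outside the arc over both regions and were not compared. Of 7667 genes, 2011 were higher and 3046 lower in NAc than in DLS at an adjusted p under 0.05 by limma. After the libraries were rescaled 2431 were higher and 2562 lower, so the excess of lower genes depends on the scaling. Each value is the smaller of the sizes that the digits allow. Higher in NAc were Timp2, a metalloproteinase inhibitor gene (1.08 ± 0.07 SE, adjusted p = 1.13e-09), Nr3c2, which encodes the mineralocorticoid receptor (1.05 ± 0.08), and Grb10, an adaptor of insulin receptor signalling (1.01 ± 0.07). For each of these all 12 NAc libraries lay above all 12 DLS libraries. Lower in NAc were Ngef, a guanine nucleotide exchange factor gene (-1.15 ± 0.06; chromosome 9, 94290729 to 94323295), Apod, an apolipoprotein gene of glia (-1.08 ± 0.08; chromosome 11, 75781496 to 75804020), and Hopx, a homeodomain-only protein gene (-0.97 ± 0.08), each in all 12 libraries. The Timp2 locus of the table (chromosome 10, 106973463 to 107021070) holds 2 genes.

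Usp45 (1.07), Hspa13 (1.06), Slc30a1, a zinc exporter gene (1.01), Fam102b (1.00), Orc3 (0.99), Usp11 (0.98) and Mgat4a (0.98) complete the 10 named as higher. Echdc2 (-1.04), Zbtb17 (-1.01), Rgl2 (-1.01), Car11 (-0.99), Plekhh3 (-0.98), Abcb9 (-0.96) and Pla2g16 (-0.95) complete those lower. Drd2 was lower in NAc (-0.66 ± 0.13, adjusted p = 0.000143), as was Fkbp5 (-0.32 ± 0.07, adjusted p = 0.000685). Drd1 did not differ beyond its error (0.05 ± 0.10, adjusted p = 0.662). Drd3, Nts, Cartpt, Cnr1, Crym and Slc17a7, fixed in advance for this comparison, were not testable at this arc and could not check the dissection. Pdyn, Penk, Tac1, Aif1, Gfap, Mbp and Tlr4 were not testable either. At an arc of 0.7 decades Pdyn stood at 1.17, Cnr1 at 0.82, Tlr4 at 0.78, Cartpt at 0.09, Gfap at -1.03 and Penk at -1.15. Libraries of these genes spanned 0.55 (Cnr1) to 0.68 (Cartpt) decades, so the direction of these values is less certain than in the main fit. Nr3c1, the glucocorticoid receptor gene, was higher (0.33 ± 0.09, adjusted p = 0.00251), but its locus holds 5 genes and its difference turned to -0.14 and -0.28 with the ribosomal index and the first component of the values as covariates.

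All 18 tested ribosomal protein genes were lower in NAc (median -0.71; Rpl23 -0.93, Rplp0 -0.59) and passed over all genes and adjusted over the list alone. Of 28 oxidative phosphorylation genes 23 fell and 2 rose (median -0.51; Cox8a -0.93, Ndufs1 0.52), and of 26 myelin genes 19 fell and 0 rose (median -0.37; Mog -0.67, Pllp -0.69). Adjusted over the list alone 25 and 19 members of these lists passed. All 3 calls by camera ended when the correlation was estimated (adjusted p = 0.785 with an estimated correlation). By fry, which tests a list without reference to other genes, they passed (adjusted p = 0.000114, 0.000561 and 9.66e-05), as did 16 of 26 lists in all. Of 11 dopamine signalling genes 1 was higher and 6 were lower, among them Gpr6 (-0.58) and Arpp19 (-0.59). Of 12 microglia markers 3 were higher and 6 lower (Spi1 -0.78, Fcer1g -0.72, C1qb -0.66), and of 17 astrocyte markers 5 were higher and 10 lower (Apoe -0.69, Cldn10 -0.63, S100b -0.61). Of 10 extracellular matrix genes 5 were higher (Hapln1 0.78, Col4a1 0.39) and 1 lower (Vcan -0.29). Of 6 GABA genes 4 were higher (Gad1 0.31, Slc32a1 0.32) and 1 lower (Gabrd -0.54). Of 14 glucocorticoid-responsive genes 2 were higher and 5 lower (Arrdc2 -0.81, Klf9 -0.68), and 5 of 9 immediate early genes were lower (Junb -0.64, Jund -0.48). These last 7 lists did not pass camera as groups, but did pass fry. Over all 7667 genes 2011 were higher and 3046 lower, so a test without reference to other genes is likely to pass many lists. Passing fry here does not set a list apart from the other genes. The ribosomal index averaged 0.34 in DLS and -0.34 in NAc, and with it as a covariate 1385 genes passed in place of 5057. All DLS libraries carry lower library numbers than all NAc libraries, so region and processing order cannot be told apart. Within each region the numbers also run group by group.

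**Figure D3:**
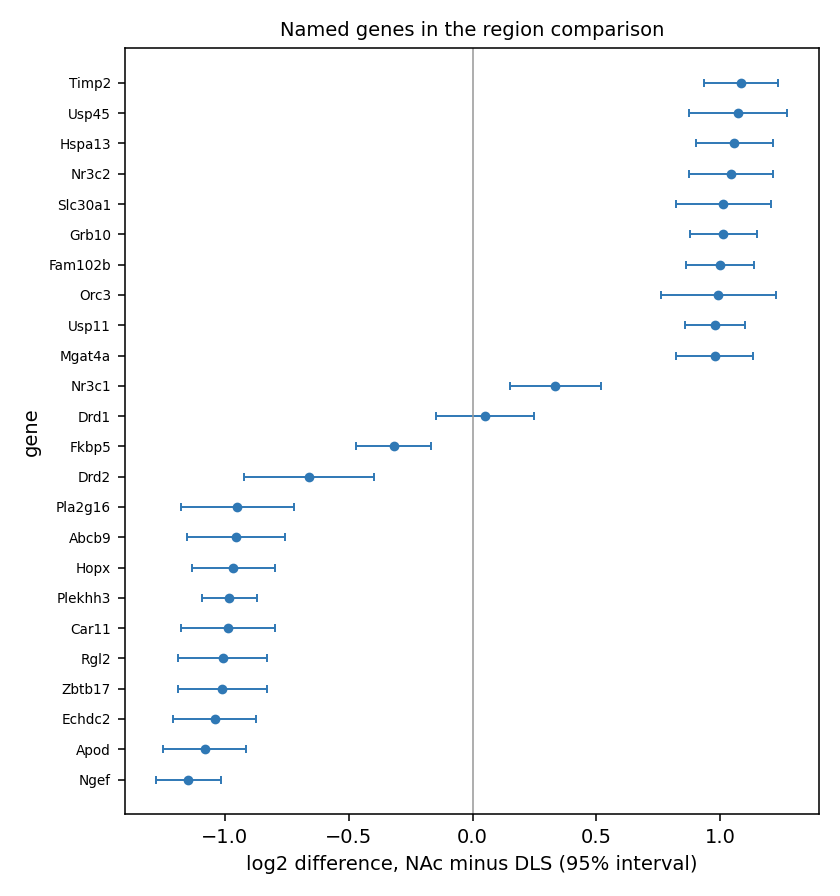
Log2 difference between regions, NAc minus DLS (horizontal axis, 95% interval), of the genes named for this comparison (vertical axis), from 12 libraries per region. Timp2 lies at 1.08 and Ngef at -1.15, while the interval of Drd1 spans 0.

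The treatment effects were also compared between the regions. For the effect of both exposures together, NAc lay below DLS in Ctss (-0.90 ± 0.27 SE), the microglial receptor gene Gpr84 (-0.73), Tmem176b (-0.72), Rnaset2 (-0.70) and Dynlt1 (-0.89), and above it in Hmcn1 (1.33 ± 0.37), Aars2 (0.90), Pus7 (0.68), Crtc2 (0.59) and Cacng8 (0.58). All 8 complement and antigen presentation genes tested in both regions lay below (median -0.61; Tap1 -0.88, B2m -0.61), with an adjusted p = 0.315 with an estimated correlation, and 3 passed adjusted over the list alone but 0 over all genes. For the stress main effect the genes were Wfs1, an endoplasmic reticulum protein gene (0.85 ± 0.23), RT1-CE5 (-0.76), Dynlt1 (-0.64), Dfna5 (0.61), Acadl (-0.59), Fkbp10 (-0.49), Hnrnph2 (0.48), Clu (-0.45), Gpn3 (0.35) and Sec13 (0.32). For the LPS main effect they were Pax6 (0.87 ± 0.28), Ctsk (-0.69), Hebp1 (-0.65), Sts, steroid sulfatase (0.59), Morn1 (-0.56), Eea1 (0.49), Cep57l1 (0.45), Fgfrl1 (0.34) and Prodh (0.33). For the interaction they were Fhl4 (-1.38 ± 0.44), Lekr1 (-1.24), Nudt22 (1.24), Capn12 (1.23), Rrad (1.09), Cope (1.07), Nfkbib (1.00), Hemk1 (0.91), Zbtb22 (0.77) and Cab39l (0.75). At the level of single genes 0 of 7667 passed with limma in each (smallest adjusted p = 0.800, 0.934, 0.993 and 0.975, in the order given), and 243, 243, 115 and 190 had an unadjusted p under 0.05. Array weights gave 2304, 570, 5 and 897 genes, and the residual component gave 289 and 7 for the first 2.

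The lists that differed between the regions at the preset correlation were, for both exposures together and besides complement genes, ribosomal protein genes (18 of 18 lower in NAc, median -0.58) and microglia markers (9 of 12 lower, median -0.31), with an adjusted p = 0.615 with an estimated correlation. Oxidative phosphorylation genes (26 of 28 lower, median -0.30), myelin genes (22 of 26 higher, median 0.22), presynaptic genes (11 of 13 higher, median 0.29) and voltage-gated channel genes (10 of 13 higher, median 0.34) had an adjusted p = 0.676 with an estimated correlation. For the stress main effect, complement genes lay lower in NAc in 8 of 8 (median -0.34; adjusted p = 0.613 with an estimated correlation). Ribosomal protein genes (18 of 18, median -0.31), microglia markers (10 of 12, median -0.15) and astrocyte markers (11 of 17, median -0.18; S100b -0.44) also lay lower, and presynaptic genes (13 of 13, median 0.21) and channel genes (12 of 13, median 0.17) higher, each with an adjusted p = 0.636 with an estimated correlation. Oxidative phosphorylation genes (26 of 28 lower, median -0.11) and myelin genes (21 of 26 higher, median 0.11) had adjusted p = 0.894 and adjusted p = 0.762 with an estimated correlation. For the LPS main effect, complement (8 of 8, median -0.24), ribosomal (18 of 18, median -0.29) and oxidative phosphorylation genes (27 of 28, median -0.18) lay lower and extracellular matrix genes higher (7 of 10, median 0.24), each with an adjusted p = 0.574 with an estimated correlation. For the interaction, oxidative phosphorylation genes had higher terms in NAc (25 of 28, median 0.45; adjusted p = 0.996 with an estimated correlation). Adjusted over the list alone 1 microglia marker passed for both exposures (Ctss) and 2 astrocyte markers for stress (Clu and S100b), 0 members passed in the other lists of this paragraph, and over all genes 0 did.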

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

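The settings with an arc of 0.7 decades and with the ribosomal index as covariate were chosen only after the results had been seen. The remaining settings here, fry among them, were planned. Of the 5 lists whose LPS main effect differed between the regions at the preset correlation, 1 passed with an estimated correlation too. It holds leptomeningeal and fibroblast markers, genes of the membranes that cover the brain and of vessel-associated fibroblasts. Their LPS main effect was higher in NAc than in DLS by a median of 0.28 log2, in 8 of 8 tested members, among them Slc6a13 (0.56), Bgn (0.41), Col3a1 (0.33) and Islr (0.25). Within the regions the medians were -0.17 in DLS and, over more members, 0.07 in NAc. The difference passed camera with the preset correlation (adjusted p = 0.00236) and with an estimated one (adjusted p = 0.0438), and did not pass fry (adjusted p = 0.136). It was 1 of 104 list tests over 4 comparisons, and adjustment was made within each comparison. With 1 of the 24 libraries left out in turn, 11 fits stayed past the threshold with an estimated correlation, with adjusted p between 0.0118 and 0.209 and medians between 0.18 and 0.35. Rescaling gave a median of 0.29 (adjusted p = 0.0487), the wider arc, with 14 members, 0.26 (adjusted p = 0.594) and the covariate 0.29 (adjusted p = 0.161), so the call ended in the last 2 without a much smaller median. Groups of 3 libraries were too small to look for single outlying values.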

How the results depend on the processing

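Arcs other than 0.5, robust empirical Bayes, covariates and the removal of 2 NAc libraries together were settings chosen only after the results had been seen. So were the regroupings under array weights and the residual component. Under rescaling, robust empirical Bayes and, for the 12 treatment comparisons, the fit of all 24 libraries, no count of genes at an adjusted p under 0.05 moved by over 1.5 times. Pseudocounts, filters on mean FPKM, a variance trend and tests on read counts were not run, since the digits give no absolute level or count. With an estimated correlation, and with directional fry, 0 lists passed in each of the 12 treatment comparisons, while mixed fry passed 1, leptomeningeal markers for the DLS stress main effect (adjusted p = 0.0238). Unless stated otherwise, the cause was not tested.

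Array weights raised the count of genes from 0 to 217 for the DLS stress main effect, 2469 for LPS alone, 1186 for stress alone and 2507 for both exposures in DLS, 634 for LPS alone in NAc, and 5, 570, 897 and 2304 for the differences between regions in the LPS main effect, the stress main effect, the interaction and both exposures. Weights ran from 0.0881 to 4.40 in NAc, where their estimation stopped before convergence, as it did over 24 libraries. The count of lists became 6 for the DLS stress main effect and 2 for both exposures in DLS, and in NAc 5 for the LPS main effect, 3 for LPS alone, 10 for stress alone and 6 for both. The first component of the residuals as covariate gave 579 genes for the DLS stress main effect, 1581 for stress alone in DLS, 722 for the NAc LPS main effect, 19 for LPS alone in NAc, and 7 and 289 for the differences in the stress main effect and both exposures, with 4 lists for LPS alone in DLS. Regrouped libraries gave calls under the same settings, for example up to 4518 genes with array weights and 3000 with the residual component for the DLS stress main effect, in 20 splits.

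An arc of 0.3 decades, which tests fewer genes, gave 2364 genes for region, and 0, 7, 3, 2 and 2 lists in DLS for the LPS and stress main effects, LPS alone, stress alone and both, with 6 and 3 in NAc for the LPS and stress main effects. An arc of 0.7 gave 1 gene for LPS alone in NAc (Spag6, -1.62), 8 lists for the DLS interaction and 12 for LPS alone in NAc. The direction of this Spag6 value is uncertain, since the way round the circle in the other direction is about as long. The ribosomal index as covariate gave 1385 genes for region, 6 and 10 lists in DLS for the LPS main effect and both exposures, and 6 and 4 in NAc for the LPS main effect and the interaction. The first component of the values gave 1926 genes for region and 13 lists for both exposures in DLS. The region difference of Nr3c1 reversed under both, to -0.14 (adjusted p = 0.280) and -0.28 (adjusted p = 0.0142). Without both NAc libraries of high ribosomal index, 6 lists passed for the LPS main effect and 4 for LPS alone.

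Without 1 library the region count ran from 4846 to 5354. The treatment and difference counts stayed between 0 and 0, except 0 to 1 for LPS alone in NAc (1 without control replicate 2, Spag6) and 0 to 1 for stress alone in NAc (1 without control replicate 3, Clock). Counts at unadjusted p under 0.05 moved more, in DLS from 108 to 347, 353 to 2162, 224 to 901, 133 to 973, 491 to 1847 and 170 to 1921 for the LPS and stress main effects, the interaction, LPS alone, stress alone and both, and in NAc from 201 to 582, 72 to 503, 124 to 1109, 225 to 904, 122 to 1779 and 127 to 609. The highest came in DLS without LPS unstressed replicate 3 (LPS main effect, interaction, LPS alone) or LPS stressed replicate 3, and in NAc without saline stressed replicate 3, or replicate 2 for the LPS main effect. The fit of all 24 libraries, over 7667 genes, gave 137, 13, 67, 121, 41 and 71 in NAc. Lists in DLS ran from 3 (without LPS stressed replicate 3) to 12 (LPS stressed replicate 2) for the LPS main effect, 5 (LPS stressed replicate 3) to 15 (LPS stressed replicate 2) for stress, 2 (saline stressed replicate 2) to 10 (saline stressed replicate 1) for the interaction, 3 (LPS unstressed replicate 3) to 7 for LPS alone, 5 to 12 (saline stressed replicate 1) for stress alone and 4 (LPS unstressed replicate 1) to 14 (LPS stressed replicate 2) for both. In NAc they ran from 6 (saline unstressed replicate 3) to 14 (LPS stressed replicate 1), 3 (LPS stressed replicate 2) to 10 (saline unstressed replicate 2), 5 (LPS unstressed replicate 2) to 11, 6 to 14 (saline unstressed replicate 2), 5 to 11 (saline stressed replicate 2) and 7 (saline unstressed replicate 1) to 14, in the same order.

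Named genes kept their direction and side of the threshold in 338 of 338 values under robust empirical Bayes, and 90 passed newly with array weights and 45 with the residual component. With the first component of the values 2 lost their call. With the ribosomal index 1 of 338 values reversed, that of Nr3c1 between regions. The other named genes that passed between regions kept their call and direction, though most were picked for large differences. Signs of values that did not pass changed in 39 with array weights, 39 with the ribosomal index, 31 with the first component and 199 of 5016 without 1 library. With the library number as a block, pairing DLS number n with NAc number n + 12, 4945 genes differed between regions. Residuals of such pairs correlated at -0.551 to 0.350 (mean -0.0147), 6 of 12 pairs were above 0.1 and 0 libraries correlated best with their own number, so the numbers were not taken as pairs. Depth is unknown, so how far it limits the counts cannot be stated.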

Other observations

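The splits of the libraries were planned, and the tests of gene length, depth, treatment, the ribosomal axis, batch and control libraries below were chosen only after the results had been seen.

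Within each region the libraries differed most along 1 axis. The first principal component took 47.7% of the variance in DLS and 48.9% in NAc. Among the genes on one side in DLS were the ribosomal genes Rps21 and Rps10, the respiratory chain genes Cox6c, Cox7c and Ndufb2, the mitochondrial import gene Tomm7, the prefoldin gene Pfdn5 and Foxs1. Against them stood Usp25, Bmpr1a, Ago2, Phkb and Pde8b. In NAc the first side held Rpl22l1, Atp5e, Mt3, Stmn3 and Pnoc, and the other Cd2ap, Vps13a, Mical3, Hecw1 and Zcchc2. Across 9031 genes, which are not independent, the loadings of the regions correlated at r = 0.769. The ribosomal and oxidative phosphorylation indices correlated over the 12 DLS libraries (r = 0.973, permutation p = 1e-05, the smallest it can give, adjusted p = 6e-05; rho = 0.888, permutation p = 0.00018, adjusted p = 0.00108; r = 0.970 without the 2 farthest libraries). In NAc the relation rested on 2 libraries (r = 0.886, permutation p = 0.00638, adjusted p = 0.0383; rho = 0.476, permutation p = 0.120, adjusted p = 0.361; r = 0.136 without the 2 farthest). Each region had 6 such relations.

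Spag6, a gene of the ciliary axoneme, lay outside the arc of 0.5 decades with all 12 NAc libraries and was looked at after its value was seen. For LPS alone in NAc it stood at -1.40 (adjusted p = 0.0246) without control replicate 2. That is the shorter way round the circle, and a larger difference in the other direction cannot be excluded.

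A bias by gene length may account for part of this axis, since the loadings fell with the span of the gene's locus (rho across genes = -0.379 in DLS and -0.455 in NAc). The rho stayed at -0.364 and -0.444 without ribosomal and oxidative phosphorylation genes, and the median span was 6762 bp in the top 10% of DLS loadings and 37489 bp in the bottom 10%. Depth could contribute in DLS, where the ribosomal index rose with the number of genes listed as 1 (r = 0.701, permutation p = 0.0120, adjusted p = 0.0361; rho = 0.587, permutation p = 0.0481, adjusted p = 0.144; r = 0.747 without the 2 farthest libraries), while in NAc the test left it open (r = -0.0809, permutation p = 0.833, adjusted p = 0.833; rho = -0.126, permutation p = 0.698, adjusted p = 0.698; r = -0.208 without the 2 farthest). Treatment could not be told apart from chance as a source (permutation p of the index over 4 groups = 0.514 in DLS and 0.586 in NAc, 12 libraries each). Locus span includes introns, so transcript length, RNA quality and dissection stay untested.

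The region difference may partly be the same axis. Of the 5057 genes that differed, 20.4% also passed with the ribosomal index as covariate, 1009 of these 1032 in the same direction, and their differences correlated with the loadings (r = -0.680 across 7667 genes). The median size among the 5057 went from 0.39 (median SE 0.0817) to 0.16 (median SE 0.109), so the calls ended through smaller differences and wider errors. The index itself differs between regions (-0.11 to 0.79 in DLS, -0.54 to 0.10 in NAc), so a biological difference between the tissues remains open. Batch remains open too, since 0 library numbers are shared by the ranges of both regions.

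Higher complement and antigen presentation genes in DLS after both exposures (median 0.43) might follow the ribosomal axis or the controls. With the ribosomal index as covariate the median was 0.36, or 83.2% of that value. The list did not pass with an estimated correlation with or without the covariate, so this decides nothing about the axis. A single control library standing apart is argued against as the whole source, since the lowest median without 1 control was 0.39. Controls that are low together, and the treatments, stay open.

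For each comparison the libraries were also split into groups of the same sizes in other ways, the real split included. In DLS, counts of genes at unadjusted p under 0.05 as large as the real one came from 78 of 100 splits for the LPS main effect (real 149, highest other 3425), 23 for stress (676, 3574) and 28 for the interaction (481, 4004). In NAc they came from 36 (377, 2424), 98 (95, 4533) and 72 (189, 3541). Counts of lists as large came in DLS from 17 (10, 18), 26 (11, 17) and 87 (4, 19) and in NAc from 49 (10, 22), 89 (6, 21) and 49 (9, 17). For the differences between regions the numbers were 80 for the LPS main effect (115, 2942), 48 for stress (243, 2542), 61 for the interaction (190, 2096) and 49 for both exposures (243, 3040). Chance cannot be excluded for any of these. The highest other splits called several times the real count of genes, which points to a structure of the samples other than the treatments. For region, 1 of 100 splits gave as many genes at adjusted p under 0.05, the real one (5057, highest other 1), and chance can be excluded.

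Against controls there are 10 splits, too few for a share under 0.05. Counts of genes as large came in DLS from 3 splits for LPS alone (real 301, highest other 2364), 1 for stress alone (1358, 386) and 3 for both (303, 3243), and in NAc from 3 (325, 611), 9 (137, 5335) and 7 (221, 734). Counts of lists as large came in DLS from 4 (7, 17), 5 (7, 14) and 9 (6, 19), and in NAc from 9 (7, 14), 10 (5, 13) and 4 (12, 18).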
